A study of Capra hircus with 2 samples.

How the data were processed

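RNA sequencing was carried out on longissimus thoracis, a muscle that runs along the back, from Chinese Xuhuai goats (Capra hircus). There were 2 libraries, 1 from fetal muscle at day 90 of a gestation of 150 days and 1 from muscle of goats aged 6 months. Per the labels' protocols, tissue was frozen in liquid nitrogen, RNA was extracted with Trizol and libraries followed standard Illumina protocols. The sampling text given for the 6-month sample repeats that of the fetal sample and describes embryo collection, so how the older muscle was sampled is not given in the sources used here. Neither is the number of animals behind each library. Each stage thus had a single library, and no difference reported below has a replicate check.

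Per the file headers, the authors deposited for each library a list of RefSeq transcript accessions with the count of unique reads, the transcript length, the percentage of the transcript covered (coverage) and the RPKM. The aligner, the counting rules, whether reads were counted by strand, the genome build and the origin of the transcript set are not given in the sources used here. The deposited counts were whole numbers of at least 1 that summed exactly to the total in the header, 12811117 unique reads for the fetal library and 9144138 for the 6-month library. An accession absent from a list therefore had 0 reads there. The authors' RPKM values, reads normalised to transcript length and to that total, were recovered from the counts within 1 part in 1000000 for all 11393 fetal and all 10850 6-month accessions. Transcript lengths were the same in both files for every shared accession. In each of the 235 fetal and 326 6-month accessions with 1 read, the covered stretch came to 90 bases within the rounding of the deposited coverage percentage, so 90 bases was taken as the span of a read.

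The files do not pair accessions with gene symbols. Of the 11663 accessions listed in either file, 0 were found in the table of goat RefSeq genes used here (assembly ARS1.2), so no gene is named and no genomic position is given. The organism of the transcript set was not established either. Before the data were examined, 30 gene lists (muscle isoforms, metabolism, cell cycle and other cell types among them) and a rule for naming genes had been fixed. The rule took, among genes with a symbol and an RPKM of at least 10 in either library, the 12 with the largest difference in each direction, the most abundant genes and list members. Without symbols, neither the lists nor the random lists planned to go with them could be used. In their place, 2 accessions in each direction are named, those with the largest differences among accessions at an RPKM of at least 10 in either library, and the rest are described by abundance.

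From the deposited values, the difference between stages was computed as log2(RPKM + 1) of the fetal library minus that of the 6-month library. This pseudocount of 1 understates the change of low transcripts. Accessions with an RPKM of at least 1 in either library were compared, and one was called higher in a library when the difference was at least 1, about 2-fold. With 1 library per stage no test across animals was possible, and no p-value was computed. For ratios of reads, exact conditional binomial (Clopper-Pearson) 95% intervals were computed. They compare these 2 libraries, not the stages, and cover counting error only, as PCR duplicates are not separate molecules. A count of 0 allowed a share of up to 2.34e-05% of the fetal reads and 3.28e-05% of the 6-month reads (3 counts of the total). The procedure was tested on simulated data with the real library totals and 200 changed accessions, all drawn at a shared RPKM of at least 2. For the fetal against 6-month comparison, 100% of accessions changed 4-fold were called in the right direction, and 5 of 9242 unchanged accessions were called. At 1.5-fold, 0% were called, which the threshold of about 2-fold largely fixes in advance. Changes of 4-fold nearer the minimum RPKM of 1 were not simulated, and there the pseudocount can keep them from being called. The simulated counts held counting error only, around a profile shared by both libraries. They had no spread between animals or library preparations and no general shift between libraries. These results check the calling rule and give no rate of false calls for the real libraries. Alternatives covered the pseudocount, the minimum RPKM, the minimum number of reads, the size threshold and 4 other scalings between libraries (transcripts-per-total scaling, centring on the median ratio, centring on a trimmed mean ratio, and library totals without the 50 most abundant accessions). Wherever the 50 most abundant accessions were left out, they were ranked by the RPKM summed over both libraries. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.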

Results

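To compare gene expression between 2 stages of goat skeletal muscle development, transcript levels of longissimus thoracis were measured by RNA sequencing at fetal day 90 and at 6 months of age. The fetal library held 12811117 unique reads over 11393 transcript accessions, and the 6-month library held 9144138 unique reads over 10850 accessions. Reads were found in both libraries for 10580 accessions, in the fetal library alone for 813 and in the 6-month library alone for 270. Accessions seen in a single library were mostly rare, with a median of 4 reads for those seen in the fetal library alone and 2 reads for those seen at 6 months alone. The accessions are not paired with gene names, so transcripts are described by abundance and, in 4 cases, by accession. Each stage was represented by 1 library, and the spread between animals is unknown.

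Reads at 6 months were concentrated on fewer transcripts than in the fetal library. The single transcript with most reads took 5.61% of the reads at 6 months and 2.83% in the fetal library. The 10 transcripts with most reads took 25.6% and 13.8%, and the top 50 took 46.1% and 29.9%, respectively. The leading 70 accessions were enough to reach 50% of the 6-month reads, whereas 184 were needed in the fetal library. The highest RPKM was 37769 at 6 months and 15478 in the fetal library. The median RPKM of listed accessions was 5.28 at 6 months and 8.23 in the fetal library, and 8452 and 9454 accessions, respectively, reached an RPKM of 1.

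**Figure D1:**
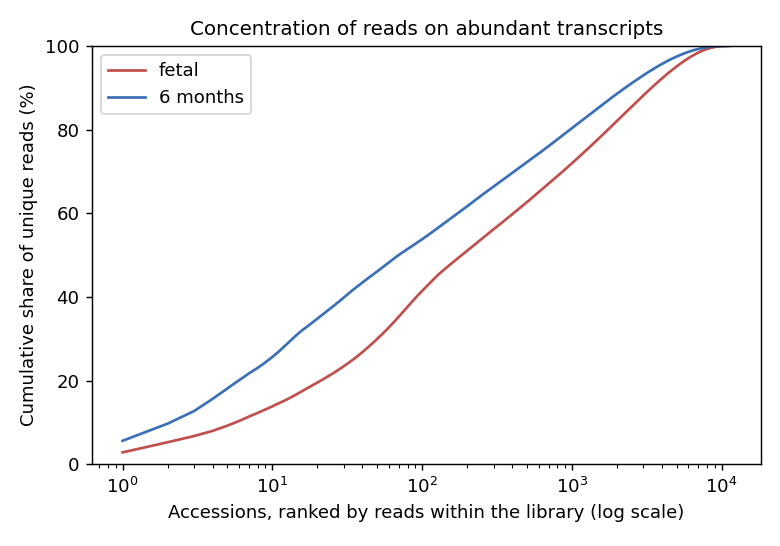
Cumulative share of unique reads (%, vertical axis) against the number of accessions, ranked by reads within each library (log scale, horizontal axis), with 1 line per library. The 6-month line lies above the fetal line, at 25.6% against 13.8% for 10 accessions and 53.8% against 41.4% for 100 accessions.

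The comparison of stages asked which transcripts differed between fetal and 6-month muscle. Of 9705 accessions compared, 3411 (35.1%) were at least 1 log2 unit higher in the fetal library, 918 (9.46%) were higher at 6 months and 5376 differed by less. The 3411 accessions higher in the fetal library accounted for 60.01% of fetal reads and 12.6% of 6-month reads. The 918 accessions higher at 6 months accounted for 59.2% of 6-month reads and 10.4% of fetal reads. A difference of at least 2 log2 units was found for 1051 accessions higher in the fetal library and for 339 higher at 6 months, and one of at least 4 units for 83 and 51. The 95% interval of the read ratio reached below 2-fold for 448 of the 3411 accessions and for 107 of the 918, so counting error leaves the size of these open. It excluded a ratio of 1 for 3409 of the 3411 and for 915 of the 918, so for the few others the direction is open too. This interval compares the 2 libraries only.

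On RPKM, which is relative to the read total of each library, most accessions were shifted toward the fetal library. At a mean RPKM of 100 to 1000 no such shift was seen, with a median difference of -0.07 log2 units. Of the 8201 accessions with an RPKM of at least 1 in both libraries, 5658 (69.0%) had the higher RPKM in the fetal library. The median log2 ratio of fetal to 6-month RPKM was 0.58 over these accessions (interquartile range -0.21 to 1.37). Relative to that shift, that is after centring on the median ratio, 2162 accessions were higher in the fetal library and 1674 were higher at 6 months. Fetal calls thus made up 56.4% of all calls after centring, against 78.8% on the deposited RPKM. The centring was set on the 8201 accessions without the pseudocount, and the minimum RPKM was applied before it. Over the 9705 accessions compared, the median difference was still 0.13 log2 units after centring. The fetal share of 56.4% is therefore not free of the shift. Across the 8201 accessions, which are not independent replicates, the RPKM of both libraries had a Spearman correlation of 0.75 and a Pearson correlation of 0.78 on the log2 scale.

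**Figure D2:**
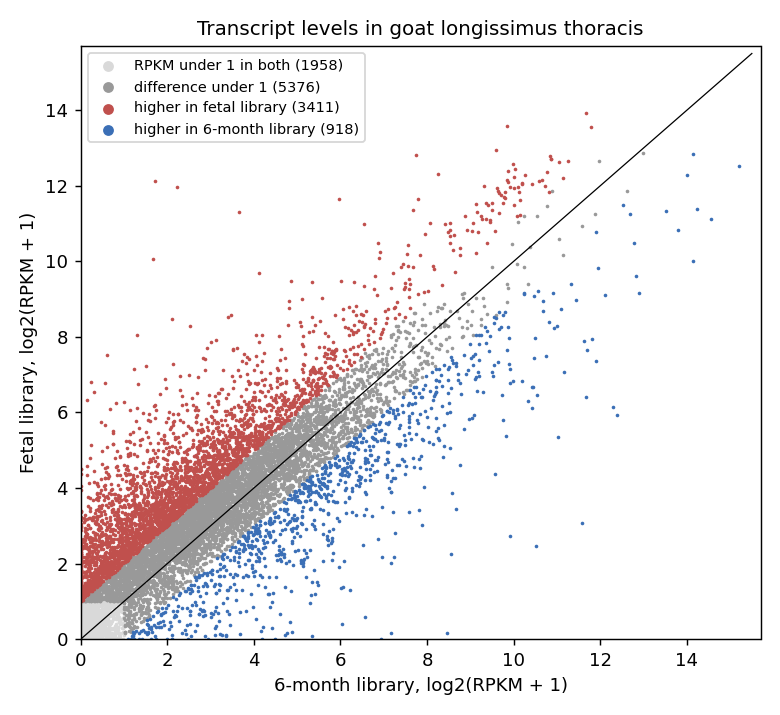
Level of each accession in the fetal library (vertical axis, log2(RPKM + 1)) against the 6-month library (horizontal axis, same unit), where each point is 1 accession and the line marks equal levels. Of the coloured points, 3411 are higher in the fetal library and 918 are higher at 6 months.

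The most abundant transcripts differed between the libraries. Of the 50 accessions with the highest RPKM in the fetal library, 43 were higher in the fetal library and 3 were higher at 6 months. Of the 50 with the highest RPKM at 6 months, 33 were higher at 6 months and 9 were higher in the fetal library. Each set was chosen by the RPKM of its own library, which in itself favours calls in that direction. In all, 16 accessions were in both sets. After centring on the median ratio, 36 of the fetal 50 were higher in the fetal library and 38 of the 6-month 50 were higher at 6 months.

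The balance of directions depended on abundance. Among 4934 accessions with a mean RPKM under 10, 1852 were higher in the fetal library and 248 at 6 months. Fetal calls remained the majority after centring (1206 against 516), but the median difference in this band was then still 0.33 log2 units. Among 4051 accessions with a mean RPKM of 10 to 100, 1313 were higher in the fetal library and 458 at 6 months. This majority was lost after centring, with 773 against 868. Among 592 accessions at 100 to 1000, 170 were higher in the fetal library and 176 at 6 months, and 120 against 249 after centring. Among 128 accessions at 1000 or more, 76 were higher in the fetal library and 36 at 6 months, and 63 against 41 after centring. These 76 accessions took 31.2% of fetal reads and 5.78% of 6-month reads. The 36 took 39.0% of 6-month reads and 5.60% of fetal reads.

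**Figure D3:**
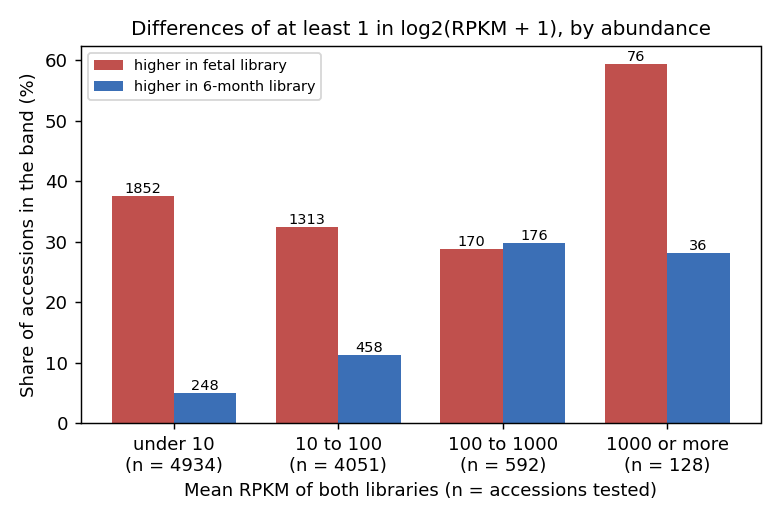
Share of accessions called higher in each library (%, vertical axis) in 4 bands of mean RPKM (horizontal axis), with the number of accessions over each bar and n for the accessions compared in each band. Fetal calls outnumber 6-month calls in the lowest band (1852 against 248) and in the highest (76 against 36), while the band of 100 to 1000 holds 170 and 176.

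Some transcripts had far lower levels in one library than in the other. The fetal library had 107 accessions at an RPKM of at least 10 that lay under 1 at 6 months, and the 6-month library had 24 of the converse kind. Of these, 102 of the 107 and 21 of the 24 still had reads in the lower library. With the minimum raised to 100, there were 3 of each kind on the deposited RPKM. After centring on the median ratio, the counts were 72 and 42 at the minimum of 10.

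The largest difference in favour of the fetal library was found for NM_001077422, a transcript of 616 bases. It had 35227 reads (RPKM 4464) in the fetal library and 13 reads (RPKM 2.31) at 6 months, a difference of 10.40 log2 units. The read share was 1934-fold higher in the fetal library (95% interval 1131 to 3633). NM_001075149, of 856 bases, had 43963 reads (RPKM 4009) in the fetal library and 29 reads (RPKM 3.70) at 6 months, a share 1082-fold higher in the fetal library (753 to 1616). In the other direction, NM_001037464, of 1851 bases, had 175 reads (RPKM 7.38) in the fetal library and 51367 reads (RPKM 3035) at 6 months. Its read share was 411-fold higher at 6 months (355 to 480). NM_001046164, of 1298 bases, had 2 reads (RPKM 0.12) in the fetal library and 4181 reads (RPKM 352) at 6 months. The ratio of 2929 in favour of 6 months had a wide interval (810 to 24192), since it rests on 2 fetal reads. Reads of NM_001077422 covered 89.9% of the transcript in the fetal library, and those of NM_001037464 covered 96.0% at 6 months.

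The 12 largest differences in each direction, among 5586 accessions with an RPKM of at least 10 in either library, ranged from 5.93 to 10.40 log2 units for the fetal library. For the 6-month library they ranged from -5.63 to -8.50. The 12 fetal transcripts had RPKM values of 79.9 to 4464 in the fetal library and of 0.11 to 11.6 at 6 months. The 12 transcripts of the 6-month library had values of 64.9 to 5357 at 6 months and of at most 69.4 in the fetal library, where 1 of them had 0 reads.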

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

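With 1 library per stage, no replicate could be left out, and the depth sets only the counting error. On the deposited RPKM, 3411 accessions were higher in the fetal library and 918 at 6 months, a fetal share of 78.8% of calls. In all 10 alternatives fetal calls stayed the majority of all calls, but not in every band of abundance. With median centring, a median difference of 0.13 log2 units was left over all accessions compared. Fetal calls then led at a mean RPKM under 10 (1206 against 516) and at 1000 or more (63 against 41). Calls at 6 months led at 10 to 100 (868 against 773) and at 100 to 1000 (249 against 120). The number higher in the fetal library changed by over 1.5 times with a pseudocount of 5 (1811), centring on the median ratio (2162), centring on the trimmed mean ratio (2157) and a threshold of 2 log2 units (1051). The number higher at 6 months did so with both centrings (1674 and 1678) and with the threshold of 2 (339). The fetal share became 73.4% with a pseudocount of 5, 76.5% with an RPKM minimum of 5 and 75.6% with the threshold of 2. By scaling, it became 75.5% with transcripts-per-total scaling, 71.1% with totals taken without the 50 most abundant accessions, 56.4% with the median ratio and 56.2% with the trimmed mean. A minimum of 20 reads, a pseudocount of 0.1 and no minimum left the share within its binomial interval, and the last changed no call by construction, since a difference of 1 needs an RPKM of at least 1. The gene list medians could not be computed under any setting because no accession had a gene name.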

Other observations

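The values for the most abundant group, for the non-coding accessions and for length after centring were chosen after the data were seen. The 76 accessions with a mean RPKM of at least 1000 that were higher in the fetal library formed a compact group. Their differences had an interquartile range of 1.70 to 2.34 log2 units around a median of 1.99. The 170 accessions higher in the fetal library at a mean RPKM of 100 to 1000 spread over 1.49 to 2.75, and the 36 accessions of at least 1000 higher at 6 months over -3.91 to -1.98. The 76 were also short, with a median length of 706 bases against 1311 for the 36 and 2074 for all accessions compared. After centring on the median ratio, 63 accessions of this band were still called higher in the fetal library. Which genes they are was not established, so no biological explanation was tested.

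Accessions with the prefix NR, which RefSeq gives to non-coding RNAs, took 0.52% of fetal and 0.25% of 6-month reads. A single accession carried 82.8% of the class's reads in the fetal library and 92.0% at 6 months, and it differed by 0.93 log2 units, less than the threshold. The other accessions of the class took 0.090% of fetal and 0.020% of 6-month reads. Of the 20 compared, 8 were higher in the fetal library, 4 were higher at 6 months and 8 differed by less, with the same counts under all 4 other scalings.

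More accessions were called higher in the fetal library (3411) than at 6 months (918). Transcript length was not the whole cause on the deposited RPKM, as the share over 4 length bins was lowest at 74.0%, but it rose with length to 84.4%, and from 50.8% to 63.6% after centring on the median ratio, so a part tied to length stays open. The abundant transcripts of the 6-month library may account for part of the shift. Leaving the 50 most abundant accessions out of both totals removed 39.7% of the median log2 ratio. With 5 to 100 accessions left out, the part removed ranged from 33.1% to 43.7%. The accessions were ranked by RPKM summed over both libraries, and the 50 held 22.3% of fetal and 33.7% of 6-month reads. The part due to the leading 6-month transcripts alone was therefore not measured. Leaving out 200 removed 51.4% and 500 removed 74.4%, but those 500 held 57.8% of fetal and 68.7% of 6-month reads, so the last value approaches centring on the other accessions. For the whole shift, including the part removed, the stage and any other difference between single libraries, chance among them, cannot be told apart, since each stage has 1 library.

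More accessions had reads in the fetal library alone (813) than at 6 months alone (270). Thinned to the 6-month total, the fetal library still had reads for 446 more accessions than the 6-month library (SD 8.95 over 20 draws). This argues against depth as the whole cause. The SD covers the random draws only, not the spread between libraries. With the 50 most abundant accessions left out and the fetal reads thinned to the 6060967 6-month reads that remained, the excess was 398. These 50 held 33.7% of 6-month reads, against 46.1% for the 50 with most reads at 6 months. A part played by the concentration of 6-month reads is therefore not excluded. A broader set of transcripts in fetal muscle or other cell types in the tissue piece remain open as untested explanations.

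Many deeply read transcripts were left partly uncovered. Across 1955 accessions with at least 20 read-bases per base in both libraries, median coverage was 89.3% in the fetal and 89.2% in the 6-month library. Coverage of the same accession was alike in both libraries (Spearman rho 0.89 across accessions), and 915 accessions were under 90% in both. This argues against RNA loss in 1 library alone as the source of these gaps. It does not settle RNA quality, since deep reading can cover a transcript even where RNA is partly lost. Among 467 accessions read to within 10% of the same depth, median coverage was 79.0% in the fetal and 80.1% in the 6-month library (211 higher and 242 lower in the fetal library). A candidate explanation is that parts of the listed transcripts differ from the goat RNA or are not transcribed in muscle, but the sequences were not analysed here. Such gaps could lower a transcript's RPKM, and whether they change the ratio between the libraries was not tested.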
